A study of Rattus norvegicus with 18 samples.

How the data were processed

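Gene expression was measured in liver RNA from adult male Sprague Dawley rats with Affymetrix arrays, 18 in all. Each of the 3 groups had 6 arrays: chow, a high fat diet (HFD), and the high fat diet with pomegranate skin extract at 150 mg per kg per day (HFD+PE). Feeding lasted 8 weeks, and the animals were fasted overnight before the livers were taken. Per the submitters' processing notes, the authors used Affymetrix Expression Console and RMA, a method that corrects background, quantile-normalizes arrays and summarizes the probes of a set; the versions are not given in the sources used here. The deposited values are log2 signals for 31099 probe sets. They ran from 2.2 to 15, and all 559782 were whole multiples of 0.1, so that they had been rounded to 1 decimal. Arrays have no read depth: the number of animals and the rounding limit the precision.

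The 57 control probe sets were left out of the tests. Of the others, 20826 named 1 gene symbol, 436 named several and 9780 named none in the platform annotation. Symbols were updated through the Entrez identifier for 20758 probe sets and through an accession for 2, while 66 were kept as annotated; 1 symbol changed. Each gene was represented by its brightest probe set, by mean over all arrays, which gave 14217 genes; 4525 of them had more than 1 probe set, and 234 had placeholder symbols that were counted but not named. No filter on dim genes was applied.

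Before groups were compared, all 153 pairs of arrays were compared with each other. In 3 pairs, chow 3 and 4, HFD 1 and 2, and HFD+PE 3 and 4, no probe set differed by over 2 log2 units, against 18 to 109 in the other 150 pairs. For each pair, switch-like probe sets were then found in the other 16 arrays, as those with a gap of at least 1.5 log2 units and at least 2 arrays on each side. Outside them, the same 3 pairs had 0 probe sets over 2 log2 units apart, and the others had 7 to 96. Of the switch-like probe sets themselves, 0 differed within the 3 pairs and 2 to 18 in the others. The arrays of each pair were therefore averaged and counted as 1 animal, which left 15 animals, 5 per group. The labels call all 18 arrays biological replicates, so this is an inference from the values. The sample descriptions hold a second number whose meaning is not given in the sources used here. It was equal within the chow pair and within the HFD pair, but was 3 for HFD+PE 3 and 1 for HFD+PE 4. The design fixed before the data were examined counted 18 separate arrays; the change was made after the arrays had been compared, and the fit of 18 arrays is kept as an alternative.

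All tests were two-sided. Groups were compared with limma 3.58.1 in R 4.3.3 (statmod 1.5.0): lmFit with 1 mean per group over the 15 animals, eBayes with the default prior, and Benjamini-Hochberg adjustment over 14217 genes per comparison at an adjusted p of 0.05. A moderated F test asked for any difference between the 3 groups. The comparisons were HFD against chow, HFD+PE against HFD, and HFD+PE against chow. The relation between the first 2 comparisons was given by the count of genes changed in opposite directions and by the correlation and covariance of log2 changes. Because they share the HFD animals, 100 simulated draws of unchanged groups and 20 splits of the 5 HFD animals, 2 for one comparison and 3 for the other, stand beside them.

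The 31 gene lists, with 665 symbols of which 595 were measured, were fixed before the data were examined. So were the thresholds, the tests and the rule for named genes. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over all lists and the 3 comparisons. An estimated correlation and fry served as further tests, and an exact permutation of each list's mean over animals was added after the arrays had been examined. With 5 animals per group, the smallest p this permutation can give is 0.00794. Members of a list were also adjusted over the list alone. The rule named up to 10 genes per direction among those past the threshold for the first 2 comparisons and up to 5 for HFD+PE against chow; where none passed, the 5 with the smallest unadjusted p were named and said not to pass. Up to 4 members with the smallest p were named for each list described.

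The lists covered oxidative phosphorylation (complex I, and complexes II to V), the TCA cycle, mitochondrial biogenesis, fatty acid oxidation, PPAR-alpha targets, fatty acid synthesis, cholesterol synthesis and uptake, bile acids and sterol transport, lipid droplets, lipoproteins, glycolysis and gluconeogenesis, insulin signalling, NRF2 and antioxidant defence, xenobiotic metabolism, acute phase proteins, inflammation, the interferon response, the unfolded protein and integrated stress response, amino acid catabolism, the circadian clock, immediate early genes and the cell cycle. Markers of stellate cells and extracellular matrix, macrophages, lymphocytes, endothelial cells, cholangiocytes, erythrocytes, hepatocytes, and adipocytes and pancreas completed them.

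The code was tested on simulated data with 14217 genes, of which 200 were changed between HFD+PE and HFD, in 3 draws with 5 animals per group. It called 100% of 4-fold and 97% of 2-fold changes, with a mean of 10.3 false calls. The simulated noise was independent between genes, and each change was equal in all 5 animals of the group. These shares are therefore not the power in the real data, where a lack of calls does not show an absence of 2-fold changes. Alternatives planned before the data were examined were array weights, a replicate block, the second number in the sample description as a covariate (its meaning is not given in the sources used here), a Welch test, renormalization, a filter on dim genes, other treatments of probe sets, another prior, fits on pairs of groups, a fold threshold, and leaving out each animal. Alternatives for shared animals, spike-in sets and RNA quality were added after the arrays had been examined. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.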

Results

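Liver gene expression was profiled in adult male rats after 8 weeks on chow, a high fat diet (HFD), or the same diet with pomegranate skin extract (HFD+PE, 150 mg per kg per day). Each group had 6 arrays, with log2 signals for 31099 probe sets. Values below are log2 levels or differences, as mean ± SD over animals or as a change with its standard error (SE).

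Within each group, 1 pair of arrays had none of the large differences seen between the other arrays. For chow 3 and 4, HFD 1 and 2, and HFD+PE 3 and 4, 0 probe sets differed by over 2 log2 units, against a median of 42 in the other 150 pairs. The SD of the difference was 0.117 for the HFD pair, with 42.9% of probe sets equal after rounding, 0.215 for the chow pair and 0.260 for the HFD+PE pair; the lowest of the other pairs was 0.260. By the overall SD alone the HFD+PE pair was thus no closer than the closest other pair. Each pair was counted as 1 animal, so that n = 5 animals per group throughout.

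**Figure D1:**
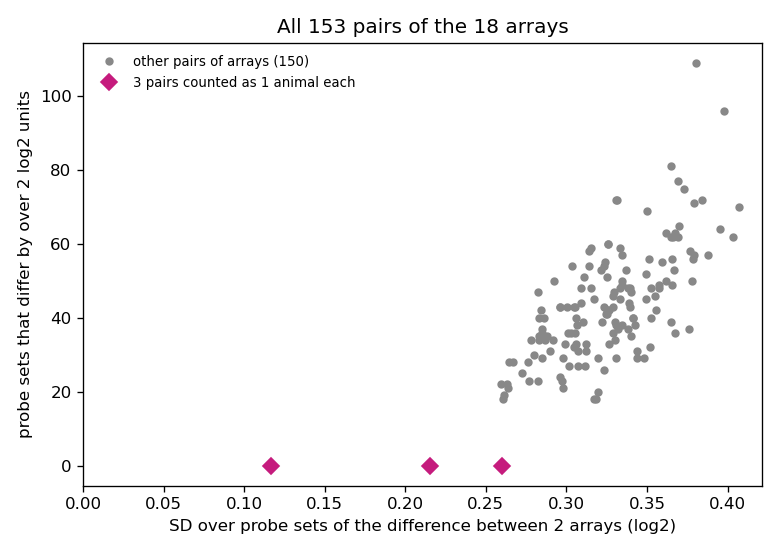
Each point is 1 of the 153 pairs of arrays. The x axis is the SD over probe sets of the difference between the arrays (log2), and the y axis is the number of probe sets that differ by over 2 log2 units. The 3 pairs counted as 1 animal each lie at 0, and the other 150 pairs lie between 18 and 109.

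The arrays also fell into sets by their hybridization controls, transcripts added to each sample before hybridization. The mean level of the bioC, bioD and cre controls was 11.88 to 12.62 on 5 arrays and 10.97 to 11.47 on 13 arrays. The high set was not uniform: a further control, bioB, was at 5.7 to 7.0 on 4 of its arrays and at 9.63 on chow 1, against 7.93 to 8.57 in the low set. The high set held 3 chow, 0 HFD and 2 HFD+PE arrays. Between the sets, 1320 of 14217 genes differed at an adjusted p under 0.05 in limma with the animal as a random block, and 749 of these were higher in the high set.

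The comparison of HFD with chow asked what the diet alone did to the liver. Genes of cholesterol synthesis and uptake fell as a group: all 20 measured members were lower on HFD, with a median change of -0.60, and all 5 HFD animals lay below the chow mean. Examples were Tm7sf2, a sterol reductase (-1.06, SE 0.42), Cyp51, the lanosterol demethylase (-0.78, SE 0.35), Acat2, which joins acetyl-CoA units at the start of the pathway (-0.74, SE 0.28), and Mvd of the mevalonate pathway (-0.73, SE 0.26). None of the 20 passed when adjusted over the list alone. The list passed limma's camera (adjusted p = 6.98e-09), but not with an estimated correlation (adjusted p = 0.618).

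Macrophage and Kupffer cell markers fell as well, with all 14 measured members lower, a median of -0.48 and 4 of 5 HFD animals below the chow mean (camera adjusted p = 3.12e-07; adjusted p = 0.593 with an estimated correlation). Among them were the complement subunits C1qa (-0.58, SE 0.20), C1qc (-0.53, SE 0.22) and C1qb (-0.56, SE 0.25), and Adgre1, which encodes the F4/80 antigen (-0.61, SE 0.26). None passed when adjusted over the list alone. The list mean of chow 2 was 1.011, against 0.069 to 0.379 in the other chow animals, and without chow 2 the mean change was -0.282 instead of -0.443.

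Genes of the unfolded protein and integrated stress response fell with a median of -0.20 in 24 measured genes, with all 5 HFD animals below the chow mean (camera adjusted p = 2.19e-05; adjusted p = 0.449 with an estimated correlation). Adjusted over the list alone, 5 fell and 0 rose. They included the endoplasmic reticulum proteins Sdf2l1 (-0.92, SE 0.23), Creld2 (-0.87, SE 0.21), Manf (-0.51, SE 0.14) and the chaperone Hyou1 (-0.46, SE 0.15). Extracellular matrix and stellate cell markers fell with a median of -0.14 over 20 genes in 4 of 5 animals (camera adjusted p = 6.1e-05; adjusted p = 0.449 with an estimated correlation). The intermediate filament gene Vim (-0.60, SE 0.13) and the metalloproteinase inhibitor Timp1 (-0.37, SE 0.09) fell when adjusted over the list alone. Ccn2, a matricellular protein, was at -0.59 (SE 0.25) and the collagen chain Col1a2 at -0.44 (SE 0.20). Interferon response genes fell with a median of -0.24 over 19 genes in 4 of 5 animals (camera adjusted p = 0.00316; adjusted p = 0.754 with an estimated correlation). The antiviral genes Oas1a (-0.67, SE 0.26), Ifit3 (-0.45, SE 0.17) and Oasl (-0.26, SE 0.14), and the transcription factor Irf1 (-0.45, SE 0.20), did not pass when adjusted over the list alone. Camera no longer called this list without chow 5 (adjusted p = 0.0973) or without HFD 4 (adjusted p = 0.0816; mean change -0.130 instead of -0.206).

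No single gene passed over all 14217. In limma, 0 genes had an adjusted p under 0.05 and the smallest was 0.315; 1088 genes had an unadjusted p under 0.05 (580 higher and 508 lower), where 711 are expected by chance. With the spike-in set as a covariate, 665 had, below the number expected. The genes with the smallest p, none of which passed, were on the higher side Enpp2, the lysophospholipase that makes lysophosphatidic acid (11.28 ± 0.28 in chow and 11.96 ± 0.25 in HFD), Ppp2r3a (0.66, SE 0.14), Mtus1 (0.43, SE 0.09), Btbd10 (0.53, SE 0.12) and Rpap2 (0.37, SE 0.08). On the lower side they were the actin-binding protein gene Tagln2 (8.41 ± 0.21 and 7.76 ± 0.23), the heat shock protein gene Hsph1 (-0.90, SE 0.18), the inositol synthase gene Isyna1 (-0.79, SE 0.16), Anxa2 (-0.45, SE 0.09) and Crip1 (-0.65, SE 0.13). All 5 list calls were lost with the estimated correlation and with fry. An exact permutation over animals cannot give a p under 0.00794, so that after adjustment at least 15 of the 93 list tests would have to pass together; its smallest adjusted p over all comparisons was 0.246, which says nothing on stability. Its unadjusted p was under 0.05 for 2 lists here, cholesterol synthesis and inflammation.

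The other 26 lists did not pass for HFD against chow, with medians from -0.15 to 0.39 and a lowest adjusted p of 0.0517. Energy metabolism lists had medians of 0.09 for fatty acid oxidation, 0.07 for the TCA cycle, 0.02 for complex I, 0.01 for complexes II to V and -0.01 for mitochondrial biogenesis. Other lipid and glucose lists had medians of 0.01 for fatty acid synthesis, -0.14 for PPAR-alpha targets, -0.05 for lipid droplets, 0.05 for lipoproteins, -0.03 for glycolysis and gluconeogenesis and -0.04 for insulin signalling. Medians were -0.06 for NRF2 and antioxidant defence, -0.08 for acute phase proteins, -0.04 for inflammation, -0.02 for amino acid catabolism, -0.15 for immediate early genes and -0.02 for the cell cycle. Among cell type markers they were -0.14 for endothelial cells, -0.04 for lymphocytes, -0.06 for cholangiocytes, -0.14 for erythrocytes, 0.08 for adipocytes and pancreas, and 0.00 for hepatocytes. The median and mean had opposite signs for mitochondrial biogenesis, hepatocyte markers and amino acid catabolism.

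**Figure D2:**
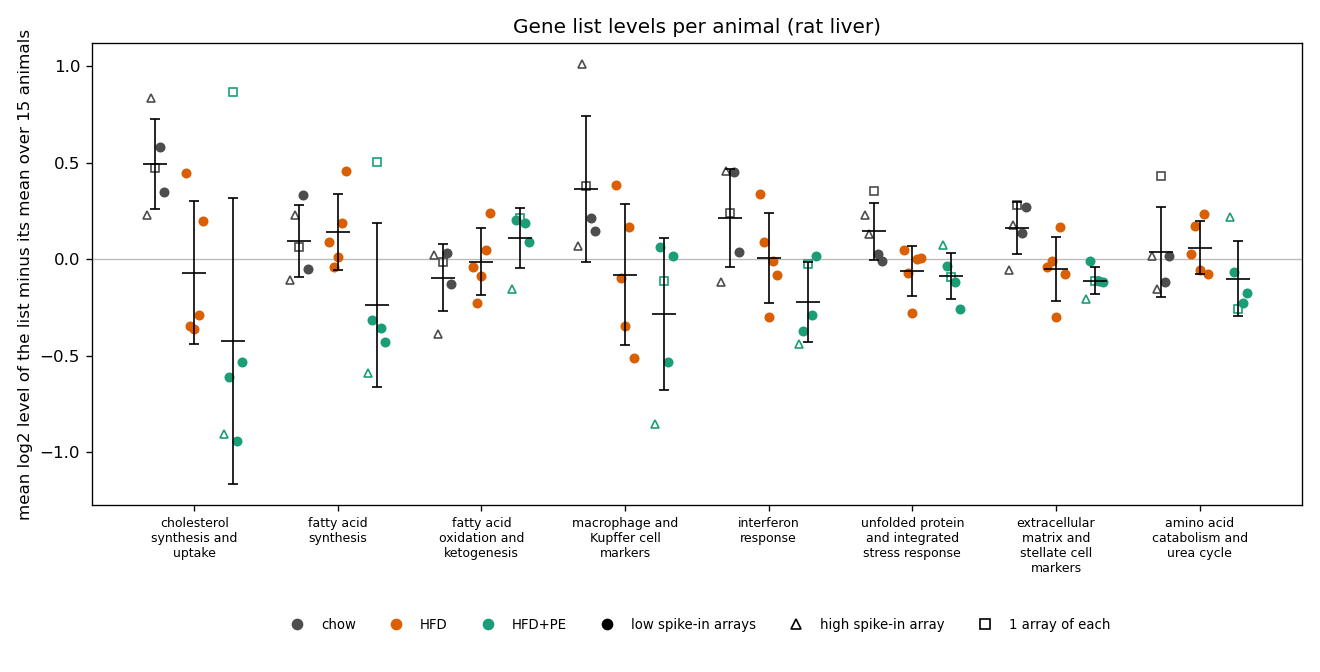
Each point is 1 animal, and its height is the mean log2 level of a gene list minus its mean over the 15 animals, for the 8 lists that passed camera in at least 1 comparison. Bars give the mean and SD of 5 animals, and marker shapes give the spike-in set of the animal's arrays. In the cholesterol list, HFD+PE 3-4 lies at 0.864 and the other HFD+PE animals at -0.939 to -0.534.

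The comparison of HFD+PE with HFD asked what the extract added to the diet. Genes of fatty acid synthesis fell as a group, with 20 of 22 members lower, a median of -0.26 and 4 of 5 HFD+PE animals below the HFD mean (camera adjusted p = 7.54e-09; adjusted p = 0.449 with an estimated correlation). The desaturase gene Scd (11.78 ± 0.65 in HFD and 10.03 ± 1.05 in HFD+PE) and Acaca, the acetyl-CoA carboxylase gene (8.48 ± 0.08 and 7.99 ± 0.37), fell when adjusted over the list alone; another probe set of Acaca had the opposite sign. Fasn, the fatty acid synthase gene, was at -0.90 (SE 0.34) and Acly, which supplies cytosolic acetyl-CoA, at -0.73 (SE 0.30), and neither passed.

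Cholesterol synthesis and uptake genes fell with a median of -0.31, all 20 lower, in 4 of 5 animals (camera adjusted p = 6.91e-07; adjusted p = 0.698 with an estimated correlation). Insig1, a sensor of sterols, was at -0.91 (SE 0.49), Cyp51 at -0.55 (SE 0.35), Acat2 at -0.52 (SE 0.28) and Ebp, a sterol isomerase, at -0.30 (SE 0.15). The mean change of -0.355 was -0.677 without HFD+PE 3-4, -0.235 without HFD+PE 1, -0.226 without HFD+PE 5, -0.225 without HFD 1-2, and -0.226 with arrays of the low spike-in set only. Interferon response genes fell with a median of -0.26 in 4 of 5 animals (camera adjusted p = 7.71e-07; adjusted p = 0.449 with an estimated correlation), with Irf7, a transcription factor of the response, at -0.55 (SE 0.22), Oasl at -0.42 (SE 0.14), Isg15 at -0.41 (SE 0.17) and Bst2 at -0.36 (SE 0.13); the mean change was -0.147 without HFD 1-2 instead of -0.230. Macrophage markers fell with a median of -0.26 in 3 of 5 animals (camera adjusted p = 0.00457; adjusted p = 0.754 with an estimated correlation), among them Clec4f, a Kupffer cell lectin (-0.45, SE 0.24), C1qc (-0.38, SE 0.22) and Csf1r (-0.36, SE 0.23), whereas the lysozyme gene Lyz2 was at 0.44 (SE 0.23). The macrophage call was lost in camera with arrays of the low spike-in set only (adjusted p = 0.334) and without any of 4 single animals: HFD 1-2 (adjusted p = 0.263), HFD 5 (0.0872), HFD+PE 1 (0.433) and HFD+PE 5 (0.0745). Its mean change of -0.204 was -0.062 on the low set, -0.088 without HFD 1-2, -0.061 without HFD+PE 1 and -0.311 without HFD 6. Among HFD and HFD+PE arrays, the low set leaves out only HFD+PE 1 and HFD+PE 3. The low-set values and those without HFD+PE 1 are therefore not separate checks.

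Fatty acid oxidation genes rose with a median of 0.10, with 21 of 23 higher, in 4 of 5 animals (camera adjusted p = 0.00133; adjusted p = 0.754 with an estimated correlation). Members were Crat, an acyl carrier enzyme gene (0.38, SE 0.20), Ech1 (0.32, SE 0.17), Bdh1 of ketone body metabolism (0.29, SE 0.12) and Decr1 (0.27, SE 0.14). Camera no longer called the list without HFD 3 (adjusted p = 0.129) or without HFD+PE 2 (adjusted p = 0.0615); the mean change of 0.122 was 0.068 without HFD 3, 0.185 without HFD 6 and 0.187 without HFD+PE 1. Amino acid catabolism and urea cycle genes fell with a median of -0.12, with 17 of 20 lower, in 4 of 5 animals (camera adjusted p = 0.00236; adjusted p = 0.691 with an estimated correlation). Among them were the serine dehydratase gene Sds (-1.03, SE 0.52), Aass of lysine breakdown (-0.41, SE 0.21), Ass1 of the urea cycle (-0.37, SE 0.17) and the glutaminase gene Gls2 (-0.25, SE 0.12). This call was lost in camera without HFD 5 (adjusted p = 0.0816). In these 5 lists other than fatty acid synthesis, no member passed when adjusted over the list alone.

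In limma, 0 genes passed over all genes and the smallest adjusted p was 0.993; 384 had an unadjusted p under 0.05, below the 711 expected by chance (600 without HFD+PE 2, 610 on the low spike-in set only, and 725 with all 18 arrays as separate animals). Those with the smallest p, none of which passed, were Pir, an iron-binding nuclear protein gene (1.12, SE 0.27), Colq (0.55, SE 0.13), the ciliary gene Bbs2 (0.48, SE 0.11), Prps2 (0.47, SE 0.12) and the nucleoporin gene Nup85 (0.30, SE 0.07), and on the lower side Scd (-1.75, SE 0.41), Sall4 (-0.54, SE 0.12), the glucocorticoid receptor gene Nr3c1 (-0.39, SE 0.11), Pdia5 (-0.38, SE 0.08) and Sox10 (-0.38, SE 0.10). Without the animal HFD+PE 3-4, Scd (-2.16) and Acly (-1.11) passed over all genes in limma (adjusted p = 0.0464 for both). The other 25 lists did not pass, with medians from -0.08 to 0.09 and a lowest adjusted p of 0.113; all 6 list calls were lost with the estimated correlation and with fry. In the exact permutation, 0 lists had an unadjusted p under 0.05. Camera's direction was down while the mean was above 0 for xenobiotic metabolism, acute phase proteins, inflammation and immediate early genes.

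The comparison of HFD+PE with chow gave the difference of diet and extract together. Cholesterol synthesis and uptake genes fell with a median of -0.84, all 20 lower, and 17 of 20 fell when adjusted over the list alone; 4 of 5 HFD+PE animals lay below the chow mean (camera adjusted p = 6.97e-18; adjusted p = 0.449 with an estimated correlation). Cyp51 fell from 11.52 ± 0.31 to 10.19 ± 0.95, Acat2 from 7.65 ± 0.42 to 6.39 ± 0.64, Mvk from 8.33 ± 0.35 to 7.71 ± 0.37 and Ebp from 10.27 ± 0.07 to 9.74 ± 0.40. Fatty acid synthesis genes fell with a median of -0.20 in 4 of 5 animals (camera adjusted p = 0.000141; adjusted p = 0.618 with an estimated correlation), and 4 of 22 fell when adjusted over the list alone: Scd (-1.64, SE 0.41), Fasn (-1.49, SE 0.34), Acss2, an acetyl-CoA synthetase gene (-0.86, SE 0.26), and Acaca (-0.73, SE 0.14). Without HFD+PE 3-4 the mean change of this list was -0.515 instead of -0.330.

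**Figure D3:**
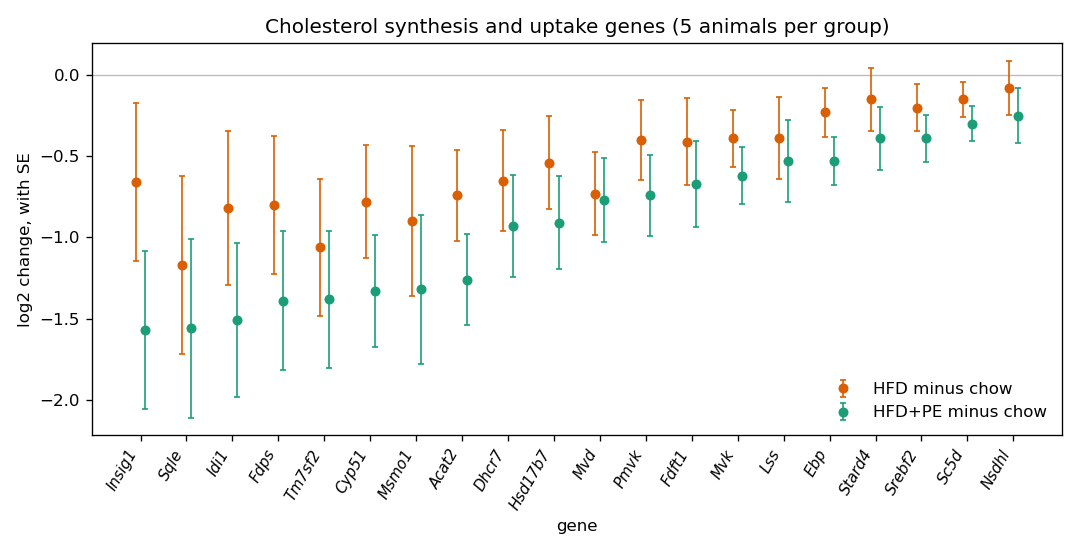
Each point is the log2 change of 1 measured gene of cholesterol synthesis and uptake, with its SE, for HFD minus chow and HFD+PE minus chow (5 animals per group). All 20 genes lie below 0 in both comparisons.

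Macrophage and Kupffer cell markers fell with a median of -0.77, with 13 of 14 lower and 9 fallen when adjusted over the list alone, in all 5 animals (camera adjusted p = 1.06e-10; adjusted p = 0.449 with an estimated correlation). Clec4f (-0.97, SE 0.24), C1qc (-0.91, SE 0.22), C1qa (-0.82, SE 0.20) and the lysosomal marker Cd68 (-0.79, SE 0.22) were among the 9. With arrays of the low spike-in set only, the macrophage median was -0.50, and the mean change was -0.394 instead of -0.647. Interferon response genes fell with a median of -0.46 in all 5 animals, 11 of 19 when adjusted over the list alone (camera adjusted p = 1.05e-09; adjusted p = 0.449 with an estimated correlation), such as Oas1a (-1.15, SE 0.26), Irf7 (-0.80, SE 0.22), Oasl (-0.68, SE 0.14) and Bst2 (-0.60, SE 0.13). Extracellular matrix and stellate cell markers fell with a median of -0.26 in all 5 animals (camera adjusted p = 4.4e-06; adjusted p = 0.449 with an estimated correlation). Ccn2 (-0.85, SE 0.25), Vim (-0.71, SE 0.13), Col1a2 (-0.64, SE 0.20) and Timp1 (-0.43, SE 0.09) were the 4 that fell when adjusted over the list alone.

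Unfolded protein and integrated stress response genes fell with a median of -0.20 in all 5 animals, 9 of 24 when adjusted over the list alone (camera adjusted p = 6.32e-06; adjusted p = 0.449 with an estimated correlation), among them Sdf2l1 (-1.05, SE 0.23), Creld2 (-0.98, SE 0.21), Hyou1 (-0.82, SE 0.15) and the chaperone Hsp90b1 (-0.53, SE 0.12). Fatty acid oxidation genes rose with a median of 0.21 in 4 of 5 animals (camera adjusted p = 5.23e-05; adjusted p = 0.754 with an estimated correlation). The peroxisomal Ehhadh (0.70, SE 0.17), Ech1 (0.52, SE 0.17) and Bdh1 (0.44, SE 0.12) rose when adjusted over the list alone, and Decr1 was at 0.38 (SE 0.14). The mean change of this list was 0.131 without chow 2 instead of 0.203.

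In limma, 0 genes passed over all genes and the smallest adjusted p was 0.104; 1584 had an unadjusted p under 0.05 (853 higher and 731 lower; 711 expected by chance). Those with the smallest p, none of which passed, were Enpp2 (0.80, SE 0.14), the acetyltransferase gene Nat8 (0.84, SE 0.14), the cholesteryl ester hydrolase gene Nceh1 (0.86, SE 0.17), Tmbim7 (0.69, SE 0.14) and Bbs2 (0.58, SE 0.11), and on the lower side Isyna1 (-0.85, SE 0.16), Hyou1, Acaca, Vim and Tagln2 (-0.60, SE 0.12). Tmbim7 was dim, at 3.0 to 3.2 in the chow animals, where array medians were 5.4 to 5.5. Whether it was above background was not tested. The count moved with several choices. With all 18 arrays as separate animals 145 genes passed, with the animal as a random block 29, and with the spike-in set as a term as well 18. Leaving out the animal HFD+PE 3-4 gave 26, and array weights gave 4. The other 24 lists did not pass, with medians from -0.13 to 0.17 and a lowest adjusted p of 0.0517 in camera. Among these, amino acid catabolism passed camera in several other settings, such as the low spike-in set only (adjusted p = 1.45e-05) and without HFD+PE 1 (0.000558). The 7 list calls were lost with the estimated correlation, where no list passed, and with fry's directional test. Fry's test of change in either direction passed 4 lists: extracellular matrix (adjusted p = 0.00114), unfolded protein response (0.00719) and interferon response (0.0245), which are among the 7, and xenobiotic metabolism (0.00097), which is not. In the exact permutation, 8 lists had an unadjusted p under 0.05: cholesterol synthesis, macrophage markers, interferon response, unfolded protein response and extracellular matrix of the 7, and bile acids, mitochondrial biogenesis and cholangiocyte markers. Macrophage markers and bile acids were at the smallest possible p, 0.00794. Here the median and mean of NRF2 genes were below 0 while camera's direction was up, and the mean of adipocyte and pancreas markers did the same.

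Across the 3 groups, the moderated F test of limma called 0 genes, with a smallest adjusted p of 0.215. The mean 3' minus 5' signal of control transcripts, a measure of RNA integrity, was 3.14 ± 0.34 in chow, 3.24 ± 0.41 in HFD and 3.38 ± 0.25 in HFD+PE; the exact permutation p against chow was 0.659 and 0.23.

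The title of the series concerns prevention by the extract, which raises the question of whether genes moved by the diet moved back. No gene passed in either comparison, so that the count of genes changed in opposite directions could only be 0. This count does not answer the question. The lists of cholesterol synthesis, macrophage markers and interferon response passed camera in both comparisons, and all 3 fell in both. With an estimated correlation none of these 6 calls passed in camera (adjusted p = 0.449 to 0.754). Single animals ended the interferon call for HFD against chow and the macrophage call for HFD+PE against HFD, as given above. The low spike-in set alone, which leaves out HFD+PE 1, ended the latter too. The log2 changes of HFD against chow and of HFD+PE against HFD had a Pearson correlation of -0.168 across genes, which are not independent replicates. Simulated unchanged groups that shared the HFD animals gave -0.503 on average (-0.536 to -0.461), and 100 random relabellings of the real animals gave -0.512 (-0.771 to -0.279). With the HFD animals split between the comparisons the mean correlation was 0.196 (0.0194 to 0.357). Shared HFD animals alone thus give a negative value, and the real one was less negative. Its sign therefore does not show that changes moved back. The covariance was -0.00374, against -0.00905 in the simulated groups, a difference of 0.00531. At an unadjusted p under 0.05 in both, 59 genes had opposite signs and 6 the same sign; the simulated means were 152 and 1.01, and independent lists would give 14.5 and 14.9. Neither is a like basis. Independent lists leave out the shared HFD animals, which favour opposite signs. The real comparisons had 1088 and 384 genes at that p, where 711 are expected of unchanged groups. These counts therefore do not show that changes moved back.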

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

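Each group of 5 animals was searched for 1 animal far from the other 4, by the gap to its nearest neighbour divided by the whole range (critical value 0.71); the test for a fault of 1 array below was chosen only after its result was seen. Of 333 such groups of named genes and list means, 24 had a far animal, where chance gives about 1 in 20.

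The animal HFD+PE 3-4 stood apart in lipid synthesis genes. Its mean was 0.864 in the cholesterol list, against -0.939 to -0.534 in the other HFD+PE animals (gap ratio 0.775), and 0.502 in the fatty acid synthesis list, against -0.587 to -0.314 (0.749). Single genes gave ratios of 0.929 for Mvd (7.6 against 6.2 to 6.3), 0.887 for Insig1 (11.15 against 8.5 to 8.8), 0.812 for Acss2 (9.9 against 8.3 to 8.6), 0.783 for Fasn (10.1 against 7.8 to 8.3) and 0.767 for Acly (11.55 against 9.4 to 9.9). A fault of 1 array is argued against: its arrays differed by 0.075 in the cholesterol list, where the gap to the next animal was 1.40. So is a chow animal under an HFD+PE label: over 50 genes chosen without it and outside both lists, it lay at 0.611 between the chow mean at 0 and the HFD+PE mean at 1, where left-out chow animals lay at 0.105 to 0.367 and the other HFD+PE animals at 0.384 to 1.0, so that the ranges nearly met. HFD+PE 3-4 also lay above all HFD animals, which were at -0.359 to 0.449 in the cholesterol list and -0.041 to 0.459 in the fatty acid synthesis list. The highest chow animals were at 0.836 and 0.331. A lower intake of the extract would at most make such an animal like HFD. The cholesterol value therefore argues against it as the whole cause, but does not exclude it with 5 HFD animals. In the fatty acid synthesis list the margin was small. Another feeding state may also set such an animal apart. Neither intake nor feeding state was tested.

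In chow 2, Enpp2 was at 10.8 against 11.3 to 11.5 (ratio 0.714), C1qa at 10.2 against 9.3 to 9.5 (0.778), Ech1 at 10.1 against 10.7 to 10.8 (0.857), and the inflammation list at 0.268 against 0.02 to 0.038 (0.927). In chow 1, the bile acid transporter Slco1a1 was at 8.4 against 8.8 to 8.9 (0.8).

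In HFD 1-2, the clock gene Per2 was at 6.75 against 9.0 to 9.3 (0.882). In HFD 5, Sox10 was at 6.2 against 5.8 to 5.9 (0.75) and Tmbim7 at 3.8 against 3.15 to 3.3 (0.769). In HFD 4, Oas1a was at 6.0 against 7.2 to 7.65 (0.727) and the lipoprotein list at -0.125 against 0.011 to 0.052 (0.767). In HFD 6, Hsp90b1 was at 11.9 against 12.2 to 12.3 (0.75).

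In HFD+PE 1, Decr1 was at 11.7 against 12.0 to 12.05 (0.857), the bile acid transporter Slc10a1 at 12.3 against 12.6 to 12.65 (0.857), the lipoprotein list at -0.166 against 0.046 to 0.087 (0.837) and the acute phase list at -0.173 against 0.007 to 0.062 (0.766). In HFD+PE 2, Ppp2r3a was at 7.5 against 7.0 to 7.1 (0.8). In HFD+PE 6, Timp1 was at 5.2 and the other animals at 5.3 (ratio 1), a difference of 1 rounding step.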

How the results depend on the processing

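The alternatives for shared animals, spike-in sets, RNA quality and the permutation of lists over animals were chosen after the arrays had been examined, although counting 18 arrays was the design fixed before. For HFD+PE against chow, where 0 genes passed in limma (1584 at an unadjusted p under 0.05), 145 passed with all 18 arrays as separate animals and 134 with only the HFD pair averaged; the F test gave 19 and 5. Both count some animals more than once if the pairs are shared, which makes p-values too small. With the animal as a random block 29 passed. With the spike-in set as a term as well 18 passed, with 1 for HFD against chow (Tagln2), 1 for the F test and a correlation of -0.278 between the log2 changes of the first 2 comparisons. The spike-in set as a covariate gave -0.297. On the low spike-in set only, 3 passed for HFD+PE against chow (A2m, Cav1, Nnmt), 1 for HFD against chow (Cav1) and 3 for the F test. Array weights gave 4 (Enpp2, Nnmt, Tagln2, Vim), and the second number of the description gave 1 (Nat8), with 1 for the F test. With the HFD animals split between the comparisons, which removes their shared chance values, the correlation turned from -0.168 to 0.196. For the other changes the cause was not tested.

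The replicate block gave 17 genes for HFD+PE against chow and a correlation of -0.277, below the highest of the other splits (-0.255), and ended the interferon call for HFD against chow (adjusted p = 0.147); the cause was not tested. The block took the first number of an animal with 2 arrays. Replicate numbers are not shown to pair animals: by that number 13 pairs had correlations of -0.139 to 0.199, and by either number 17 pairs had -0.228 to 0.199; 5 exceeded 0.1.

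List calls, 5, 6 and 7 in the 3 comparisons, fell to 0, 0 and 0 with an estimated correlation and with fry. An exact permutation over animals gave 0, 0 and 0 as well, but its smallest possible p is 0.00794, so that at least 15 of 93 tests would have to pass together; this says nothing on stability (2, 0 and 8 lists had an unadjusted p under 0.05). For HFD against chow they rose to 10 with the spike-in covariate, 10 on the low set and 9 with the 3' to 5' covariate; the cause was not tested. Of 306 camera values of the 18 list calls under settings other than an estimated correlation, 11 did not pass, all for interferon genes in HFD against chow or for macrophage, fatty acid oxidation or amino acid genes in HFD+PE against HFD. Of 3190 values of named genes under other settings, 0 changed sign and 104 passed. Named genes were chosen by their p in these same data, so that the lack of sign changes says little on stability. The passes included 26 with all 18 arrays as separate animals, 27 with only the HFD pair averaged, 14 with the animal as a random block and 13 without HFD+PE 3-4.

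Leaving out 1 animal at a time gave 0 to 1 genes for HFD against chow (1 without HFD 1-2, Hsph1), 0 to 2 for HFD+PE against HFD (2 without HFD+PE 3-4) and 0 to 26 for HFD+PE against chow (26 without HFD+PE 3-4, 2 without HFD+PE 1, 1 without HFD+PE 2, 1 without chow 5). The F test gave 0 to 12 (12 without HFD+PE 3-4, 1 without HFD 1-2, 1 without HFD+PE 1). The correlation ran from -0.368 without HFD 1-2 to -0.105 without HFD+PE 3-4. Lists ran from 5 to 8 (8 without chow 5), 5 to 9, and 7 to 11 (11 without chow 2). The other planned settings, a Welch test per gene among them, gave 0 genes in every comparison.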

Other observations

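Tests chosen only after their result was seen were those of the spike-in set, RNA quality, the share of hepatocytes, the pairs of arrays, the splits for the correlation, and all splits with the spike-in set as a covariate. Drug and alcohol metabolism genes had no shift in 1 direction past the threshold (medians 0.04 for HFD against chow, -0.02 for HFD+PE against HFD and 0.01 for HFD+PE against chow; camera adjusted p = 0.203, 0.97 and 0.322). Fry's test of change in either direction passed for HFD+PE against chow (adjusted p = 0.00097), and single members passed when adjusted over the list alone. Against chow, the retinaldehyde dehydrogenase gene Aldh1a1 rose by 1.15 (SE 0.36) on HFD and by 1.77 (SE 0.36) on HFD+PE. The glucuronosyltransferase gene Ugt2b1 was at -1.45 (SE 0.38) and -1.47 (SE 0.38), past that threshold in both. The alcohol dehydrogenase gene Adh1c rose on HFD (0.36, SE 0.10); Cyp2e1, an ethanol-oxidizing cytochrome (0.63, SE 0.14), and the monooxygenase gene Fmo1 (0.89, SE 0.27) rose on HFD+PE. Whether these changes differed between HFD and HFD+PE was not shown, since no member passed in that comparison.

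Circadian clock genes had a median of 0.39 for HFD against chow and narrowly missed the threshold in camera (adjusted p = 0.0517; adjusted p = 0.593 with an estimated correlation). The list passed camera on the low spike-in set only (adjusted p = 0.00507), with the spike-in set as a covariate (0.0374), with array medians subtracted (0.0363), with all 18 arrays as separate animals (0.0447), and without HFD 1-2 (0.00872), chow 2 (0.000498) or chow 5 (0.0367). It did not pass with dim genes left out, with the 3' to 5' signal as a covariate, with fry, or without any other single chow or HFD animal. HFD 1-2 had a list mean of -0.202, against 0.136 to 0.323 in the other HFD animals. For HFD+PE against chow (adjusted p = 0.195 in camera), the list passed at the preset correlation on the low set (0.0437) and without chow 2 (0.00975). With an estimated correlation over all animals, no list passed in that comparison. Members for HFD against chow were Per3 at 1.10 (SE 0.47; another probe set had the opposite sign), Per2 at 1.09 (SE 0.43), Tef at 0.65 (SE 0.24) and Nr1d2 at 0.52 (SE 0.17). In bile acid synthesis and sterol transport, the medians were 0.05, 0.08 and 0.17 in the 3 comparisons (camera adjusted p = 0.411, 0.203 and 0.11). Abcg5, part of the sterol exporter of the canalicular membrane, rose by 1.16 (SE 0.28) in HFD+PE against chow when adjusted over the list alone. The transporter genes Slco1a1 (0.38, SE 0.13) and Slc10a1 (0.23, SE 0.09), and Slc27a5 (-0.43, SE 0.16), did not pass.

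The 6 lists that were lower in HFD+PE than in chow were weighed against technical explanations. The spike-in set is argued against as the whole cause. The set effect times the difference in the share of high-set arrays gave at most 5.86% of a list's change. All 6 lists also passed camera at the preset correlation on the low set, which leaves out chow 1, chow 2 and HFD+PE 1. This pass adds little: with all animals, 58 of 100 splits gave camera at least as many lists as the real groups, adjusted within the comparison. With an estimated correlation over all arrays, none of the 6 passed (adjusted p = 0.449 to 0.618). The macrophage mean was smaller on the low set, -0.394 instead of -0.647. RNA quality is argued against too, since at least 83.6% of each change was kept with the 3' to 5' signal as a covariate. For macrophage markers, a larger share of hepatocytes in the piece of liver would lower other cell types alike. Endothelial markers had a mean change of -0.063 (members -0.39 to 0.26), against -0.647 for macrophage markers, a difference of -0.58. Its exact permutation p of 0.0159 argued against this explanation under the criterion first used; the adjustment over 5 such differences was put in after that p was seen and gave 0.0795, and this explanation is left open. The endothelial difference was the largest of the 5. The others were -0.524 for cholangiocytes, -0.519 for erythrocytes, -0.517 for lymphocytes and -0.374 for stellate cells and matrix. Their unadjusted permutation p-values were 0.0635, 0.119, 0.0556 and 0.167. All 5 HFD+PE animals lay above the chow mean in hepatocyte markers and below it in cholangiocyte and stellate cell markers. For endothelial markers 3 of 5 lay below it. A biological effect of diet and extract, which the design names, stays open as well.

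In the 3 close pairs of arrays, 0 of 28 to 30 switch-like probe sets differed, against a median of 10 (2 to 18) in the other pairs, which is what 2 arrays of 1 animal would give; the labels do not say so. These probe sets were found without the pair, and the other probe sets alone picked out the same 3 pairs. The spike-in sets may mark a batch of hybridization, although chow 1 stood apart within the high set in the bioB control (9.63 against 5.7 to 7.0): the high minus low differences within chow 3-4 and within HFD+PE 3-4 correlated across genes (r = 0.364), and genes are not independent replicates.

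A hypothesis of shared regulation of lipid synthesis per animal was tested on deviations from the group means over 15 animals. The cholesterol and fatty acid synthesis lists varied together (Pearson r = 0.860, permutation p = 0.00037; Spearman rho = 0.714, permutation p = 0.00344; 1 relation computed). Without the 2 farthest animals r was 0.811, and over the 12 animals with low-set arrays it was 0.843. These values are consistent with a common control of both pathways that differs between animals fed alike.

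Animals of each comparison were regrouped into 100 splits, the real one included. For genes at an unadjusted p under 0.05, chance is argued against but not excluded for HFD+PE against chow. The splits were not adjusted for the number of counts tested. Of 100 splits, 2 reached the real 1584 (highest other 1871). That other split also parted the high spike-in arrays more unevenly than the real one. With the spike-in set as a covariate in every split, it gave 670 genes and the real split 1445, which 1 of 100 splits reached, the real one (highest other 1280). Chance is not excluded for HFD against chow (19 splits reached 1088; highest other 1701), for HFD+PE against HFD (97 reached 384; highest other 1410), or for the F test (7 reached 1157; highest other 1898). With the covariate, 51 splits reached the 665 genes of HFD against chow (highest other 1584), and 86 reached the 492 of HFD+PE against HFD (highest other 1435). The split with 1410 genes gave several times the real count, and may follow a structure among the animals other than the groups, which was not tested. Counts of 0 genes after adjustment are reached by any split (100 of 100 in each case), which decides nothing; the highest others were 1, 6 and 3 in the 3 comparisons and 19 for the F test. For lists, adjusted within a comparison, chance is not excluded: 68 splits reached 5 (highest other 15), 63 reached 6 (highest other 14) and 58 reached 8 (highest other 14). The correlation of -0.168 between the log2 changes was set against a second draw of relabellings of the same animals, which is not a test apart from the first. Of 100, 1 reached it, the real one (highest other -0.255), so that chance is argued against but not excluded for it as fitted. The count was of splits with a correlation at least as high, and the first relabellings gave -0.512 on average. The departure was thus toward a less negative value, which is no sign of changes moving back. With the spike-in set as a covariate in every split the correlation was -0.297, which 3 of 100 reached (highest other -0.145). It was -0.278 with the spike-in set as a term and the animal as a random block, and -0.368 without HFD 1-2; both lie below -0.255, and no split was refitted in those ways.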
